A study of Mus musculus with 9 samples.

How the data were processed

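RNA from frozen mammary tissue of 9 female mice was labelled and put on Affymetrix Mouse Gene 2.0 ST arrays by the submitters. The deposited table holds 41345 probe sets on each of 9 arrays, in log2 units, without missing values. Per the submitters' processing notes the values were made with RMA, which corrects background, equalises the arrays' distributions and summarises the probes of a probe set. The RMA version, the probe set level and the genome build are not given, so no coordinates are printed. The scanner files were not used here. Arrays have no read depth, and their number limits the precision.

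A probe set annotation named 25335 probe sets, of which 23521 had exactly 1 gene symbol and 1814 had several, while 16010 were not listed. Of the single-symbol probe sets, 23328 matched a current Entrez gene and 193 did not. A RefSeq gene table was used for names only. Where a gene had several probe sets (1082 genes of 22180), the probe set with the highest mean over the 9 arrays stood for it. A gene was kept if it lay above its array's 30th percentile on at least 3 arrays, which removed 4702 genes and left 17478. The values were not normalised further.

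Groups were taken from the sample titles, and replicate numbers were not taken as pairs because they name different mice. A linear model with 1 mean per group was fitted to all 9 arrays in limma 3.58.1 under R 4.3.3, with 6 residual degrees of freedom, followed by eBayes without trend or robust option. The 4 contrasts were metastatic against non-metastatic tumour, each tumour group against normal gland, and the mean of both tumour groups against normal gland. All tests were two-sided, p was adjusted by Benjamini-Hochberg over the genes tested, and the threshold was an adjusted p under 0.05 without a minimum change. The SE printed beside the change of a gene is limma's moderated SE. Beside differences of list means in the closing section, it is the ordinary SE of a difference of group means over the 6 tumours.

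Gene lists of pathways, cell types and tissue markers, 36 in number, were fixed before the data were examined, as were the filter, the contrasts, the threshold and the rule for naming genes. Lists with at least 5 measured members (35 lists) were tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. Camera with the correlation estimated per list and fry were alternatives. Members past the threshold were counted both over all genes and adjusted over the list alone. Further marker lists were written after the data had been seen, for tests in the closing section.

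The naming rule took, for each contrast, the 10 highest and 10 lowest changes among genes past the threshold without overlap between the groups. Where fewer than 10 genes passed, it also took the 10 highest and 10 lowest with an unadjusted p under 0.01 and no overlap. Up to 4 members with the largest change were taken from each list described, and Wnt1 in every case. Predicted or uninformative symbols were counted and not named. Mylk was named outside this rule, after its value was seen.

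Ages were compared with an exact permutation test of the difference of means. The alternatives tried were no filter and a 50th percentile filter, the mean of a gene's probe sets, every probe set tested on its own, quantile normalisation, median centring, an intensity trend and the robust option in eBayes, array weights, only the groups compared in the fit, the replicate number as a block, age at collection as a covariate, an adjusted p under 0.1, a minimum log2 change of 1, and each array left out in turn.

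The fits were tested on simulated data with the genes' own spread, in which 200 of 17478 genes were changed. This noise was independent between genes and arrays, so the recovery and false calls below do not cover noise correlated between genes. Changes of 1 on the log2 scale were recovered in 64% of cases between the tumour groups, 68% and 57% for non-metastatic and metastatic tumours against normal gland and 69% for all tumours, and changes of 2 in 90%, 89%, 93% and 95%. No call had the wrong sign, and false calls numbered 11 of 165, 11 of 168, 13 of 163 and 6 of 170. For the list tests, 50 draws without any effect were made. With independent noise the preset camera called a median of 0 lists. With noise as correlated as the residuals it called a median of 11 and at most 19, while camera with an estimated correlation called a median of 0 and at most 2.

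Probe sets without a single gene symbol were left out of the main comparisons for want of a name, and are counted in the closing section. The erythroid list was not tested because too few members were measured.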

Results

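Gene expression was measured on Mouse Gene 2.0 ST arrays in 9 female FVB mice, with 1 array per mouse. The 3 groups held 3 arrays each: normal mammary glands of wild-type littermates, and mammary tumours of MMTV-Wnt1 mice recorded as non-metastatic or as metastatic. MMTV-Wnt1 mice carry Wnt1, a secreted signalling protein, under a mammary tumour virus promoter. Mice of both genotypes drank sucrose solution with doxycycline, and no tetracycline-regulated transgene is given in the sources used here. Array medians lay between 5.80 and 5.94 on the log2 scale, and the median SD of a gene within a group was 0.19 in normal glands, 0.19 in non-metastatic tumours and 0.14 in metastatic tumours (n = 3 each). The first principal component held 48.9% of the variance and parted the 3 normal glands from the 6 tumours, while non-metastatic tumour 3 correlated more with metastatic tumours 1 and 3 (r = 0.970 across genes with each) than with non-metastatic tumours 1 and 2 (r = 0.944 and 0.942). Non-metastatic tumour 2 also correlated more with metastatic tumour 1 (r = 0.963) than with non-metastatic tumours 1 and 3 (r = 0.957 and 0.942). Genes are not independent replicates, so these r values describe the arrays only.

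Normal gland 2 stood apart from the other normal glands. Its score for skeletal muscle markers was 3.15 against -0.74 and -0.41 in normal glands 1 and 3, and its score for differentiated epidermis markers was 3.14 against -0.76 and -0.90. Its score for milk proteins and secretory genes was -2.49 against 0.91 and 1.06. A score is the mean over the list's genes of the log2 value minus the gene's mean over the 9 arrays. Every comparison with normal gland below rests in part on this array. The arrays measured pieces of tissue, so in these comparisons a different share of cell types cannot be told apart from a change within cells.

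The tumour groups did not differ detectably in age. Mice with metastatic tumours were 288.3 ± 10.2 days old at collection (SD, n = 3) and those with non-metastatic tumours 291.3 ± 66.3 days, a difference of -3 days (exact permutation test, two-sided, p = 1). Tumour onset came at 229 ± 30.6 days in the metastatic group and at 248.3 ± 57.0 days in the non-metastatic group (exact permutation p = 0.7), and collection followed after 59.3 ± 24.2 and 43 ± 11.4 days (exact permutation p = 0.5). The difference in age at collection was 28.3 days without non-metastatic tumour 1 and -37.7 days without non-metastatic tumour 2, and that in age at onset 9.5 and -47.5 days. The difference in the interval between them, 16.3 days, was 2.5 days without metastatic tumour 2 and 25 days without metastatic tumour 3. With 3 mice against 3 the smallest p these tests allow is 0.1. The normal glands came from older mice, at 542.3 ± 12.1 days, so age and tumour status cannot be separated in any comparison with normal gland.

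Wnt1 (probe set 17314666) had the highest log2 change of all genes tested in each tumour group against normal gland. It averaged 5.59 ± 0.13 in normal glands, 12.02 ± 0.33 in non-metastatic tumours and 11.75 ± 0.48 in metastatic tumours (log2, SD, n = 3 each). The change from normal gland was 6.43 (SE 0.25, adjusted p = 2.9e-05) in non-metastatic tumours and 6.16 (SE 0.25, adjusted p = 4.0e-05) in metastatic tumours, with all 6 tumours above all 3 normal glands. Between the tumour groups Wnt1 differed by -0.26 (SE 0.25, adjusted p = 0.91). Whether the probe set covers the transgene or the endogenous transcript alone is not given in the sources used here.

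**Figure D1:**
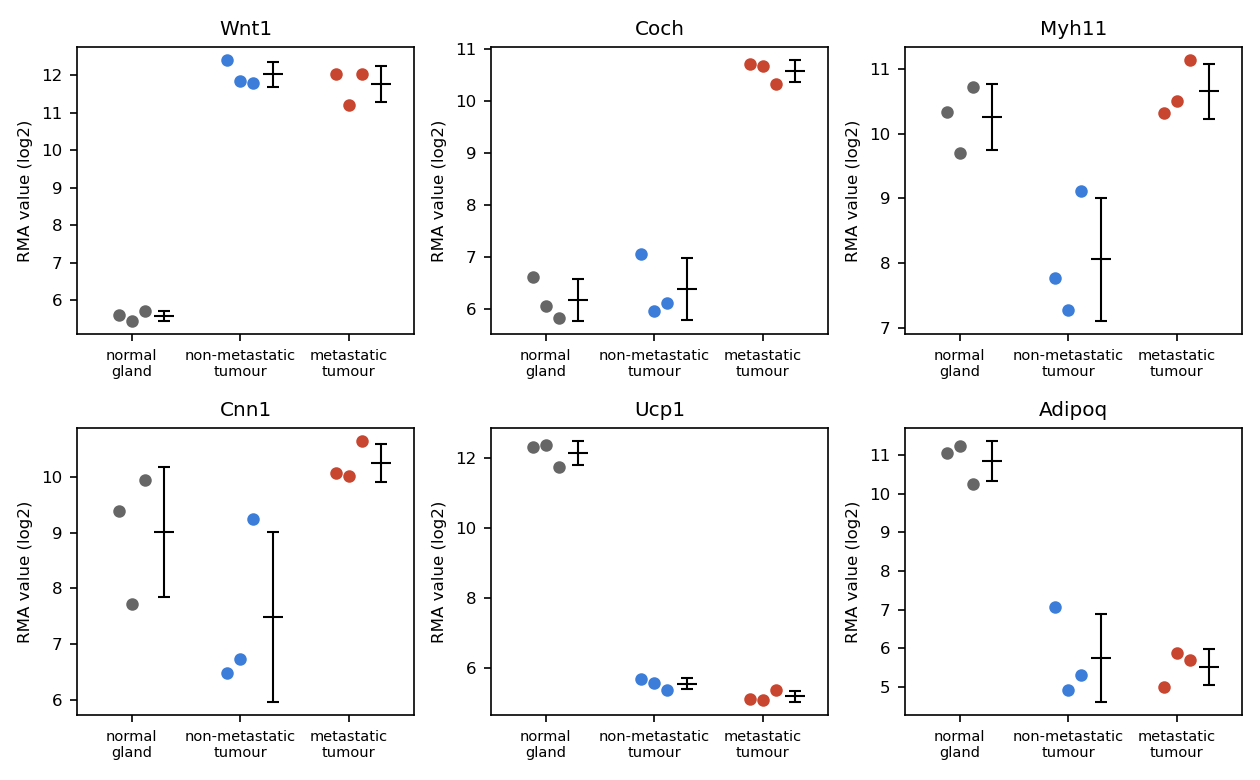
RMA values (log2) of 6 genes on the 9 arrays. Points are arrays, and the bar beside each group is its mean with the SD (n = 3). Coch averages 10.57 in metastatic tumours against 6.39 in non-metastatic tumours, and Ucp1 averages 12.14 in normal glands against 5.56 in non-metastatic tumours.

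The comparison that the series title names, metastatic against non-metastatic tumours, gave 1 gene past the threshold. Coch (probe set 17275378), which encodes cochlin, a protein of the extracellular matrix first known from the inner ear, rose by 4.18 on the log2 scale (SE 0.31, adjusted p = 0.013). It averaged 10.57 ± 0.21 in metastatic tumours, 6.39 ± 0.59 in non-metastatic tumours and 6.18 ± 0.40 in normal glands (SD, n = 3 each), and it was higher in 3 of 3 metastatic tumours than in all other arrays. Across all 17478 genes tested with limma, 886 had an unadjusted p under 0.05 where 873.9 would be expected by chance, and 10.3% had no overlap between the groups where chance gives 10%. The Coch call was lost without normal gland 2 (adjusted p = 0.063), without metastatic tumour 1 (0.081) and without metastatic tumour 2 (0.14). It was also lost with only the groups compared in the fit (0.15) and with age as a covariate in that fit (0.096). Both of these fits left out the normal glands, so the loss with the covariate cannot be credited to age. Its log2 change stayed between 3.97 and 4.52 over 21 alternatives, with adjusted p between 0.0046 and 0.15. Without non-metastatic tumour 3 the count became 40 genes, 36 of them higher, and it was 2 without non-metastatic tumour 2 or metastatic tumour 3.

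Several other genes had large differences between the tumour groups but did not pass the adjusted threshold. Ntrk3, the receptor for neurotrophin-3, was 3.26 higher in metastatic tumours (SE 0.48, adjusted p = 0.36), at 9.39 ± 1.01 against 6.13 ± 0.51, with normal glands at 8.96 ± 0.26 (SD, n = 3 each). Adgrg2, an adhesion G protein-coupled receptor, was 3.06 higher (SE 0.45, adjusted p = 0.36). Scgb1b27, a secretoglobin, was 5.38 higher (SE 1.19, adjusted p = 0.88), with values of 10.40, 13.05 and 7.24 in the 3 metastatic tumours against 4.89, 5.09 and 4.55. Foxa1, a transcription factor of luminal epithelial cells, differed by 3.03 (SE 0.77, adjusted p = 0.88), with means of 9.67 in metastatic tumours, 6.64 in non-metastatic tumours and 8.81 in normal glands. Among genes with an unadjusted p under 0.01, 140 were higher in metastatic tumours and 33 lower, and the total of 173 lay at the 174.8 expected by chance.

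Basal and myoepithelial markers were also compared between the tumour groups. Of the 17 measured members, 0 passed the threshold over all genes, 4 rose when adjusted over the list alone, and 14 had a positive difference, with a median of 0.92. These 4 were Cnn1, Myh11, Acta2 and Mylk (the last chosen after its value was seen), which build the contractile apparatus of smooth muscle and myoepithelial cells. Cnn1, the actin-binding protein calponin, was 2.76 higher (SE 0.79), and Myh11, the smooth muscle myosin heavy chain, 2.59 higher (SE 0.48). Myh11 averaged 10.65 ± 0.43 in metastatic tumours, 8.06 ± 0.95 in non-metastatic tumours and 10.25 ± 0.51 in normal glands (SD, n = 3 each). The score of the whole list was -0.94, -0.36 and 0.34 in non-metastatic tumours 1, 2 and 3. In metastatic tumours 1, 2 and 3 it was 0.77, 0.64 and 0.26, so the tumour groups overlapped. The mean of 5 contractile genes of the list, picked after their values were seen, lay at 7.94, 7.54 and 9.54 in non-metastatic tumours 1, 2 and 3. That mean lay between 10.11 and 10.49 in metastatic tumours, and between 8.98 and 10.04 in normal glands. Camera with its preset correlation gave an adjusted p = 9.8e-05 for the list, and adjusted p = 0.45 with an estimated correlation. Without non-metastatic tumour 1 the list's median difference was 0.41, and without non-metastatic tumour 3 Myh11 passed over all genes (adjusted p = 0.037).

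Interferon-response genes had the opposite sign. Of 16 measured members, 0 passed over all genes, 0 passed when adjusted over the list alone, and the median difference was -1.09, with Ifit1 at -1.79 (SE 0.89) and Oas2 at -1.93 (SE 1.17). Camera gave adjusted p = 9.7e-05 for this list, and adjusted p = 0.71 with an estimated correlation. The list score was 2.43 in non-metastatic tumour 1 and between -0.53 and -0.02 in the other 5 tumours. Without non-metastatic tumour 1 the median difference shrank to -0.17, with Ifit1 at -0.54 and Oas2 at -0.32, and camera's adjusted p was 0.035. Genes of the FGF pathway had a positive median of 0.21 over 18 members, 0 of which passed over all genes and 1 when adjusted over the list alone. That gene was Fgf1, a fibroblast growth factor, at 1.08 (SE 0.21). Without non-metastatic tumour 3 the list's median was 0.55 and Fgf1 passed over all genes (adjusted p = 0.050). For this list camera gave adjusted p = 6.6e-04, and adjusted p = 0.61 with an estimated correlation.

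In all, camera with its preset correlation called 15 of 35 lists between the tumour groups, 9 higher and 6 lower in metastatic tumours, and 0 lists passed with an estimated correlation. In simulated data without any effect but with the residuals' correlation, the preset test called a median of 11 lists and reached 15 or more in 10 of 50 draws. The 15 calls are therefore within what correlated noise gave. Targets of canonical Wnt signalling (median 0.23 over 26 members, 0 past over all genes and 0 adjusted over the list alone) had camera adjusted p = 0.0018, and adjusted p = 0.68 with an estimated correlation. The lists of hypoxia and glycolysis genes (median -0.41 over 16 members, camera adjusted p = 3.0e-04, and adjusted p = 0.68 with an estimated correlation) and of antigen presentation genes (median -0.41 over 12 members, camera adjusted p = 0.0050, and adjusted p = 0.72 with an estimated correlation) also had 0 members past over all genes and 0 adjusted over the list alone. Basal, interferon-response and FGF lists were called with each array left out in turn, although their size moved as given above, and the other 12 were not. Without non-metastatic tumour 2 the calls of Wnt targets (adjusted p = 0.12, median 0.079) and of hypoxia genes (adjusted p = 0.11, median -0.18) were lost, and without non-metastatic tumour 1 those of antigen presentation (adjusted p = 0.78, median -0.12), cell adhesion (0.14) and Notch pathway genes (0.052). The median of Wnt targets was 0.57 without non-metastatic tumour 3, and that of antigen presentation genes -0.78 without non-metastatic tumour 2. The cell division, mesenchymal transition, neutrophil, blood and lymphatic endothelial, skeletal muscle and TGF-beta lists were each lost without any of several arrays, with adjusted p up to 0.98. Genes described as promoters (22 measured) and as suppressors (12 measured) of metastasis had 0 members past over all genes and 0 adjusted over the list alone. Camera gave adjusted p = 0.49 and 0.29 for these lists, and adjusted p = 0.74 and 0.72 with an estimated correlation.

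**Figure D2:**
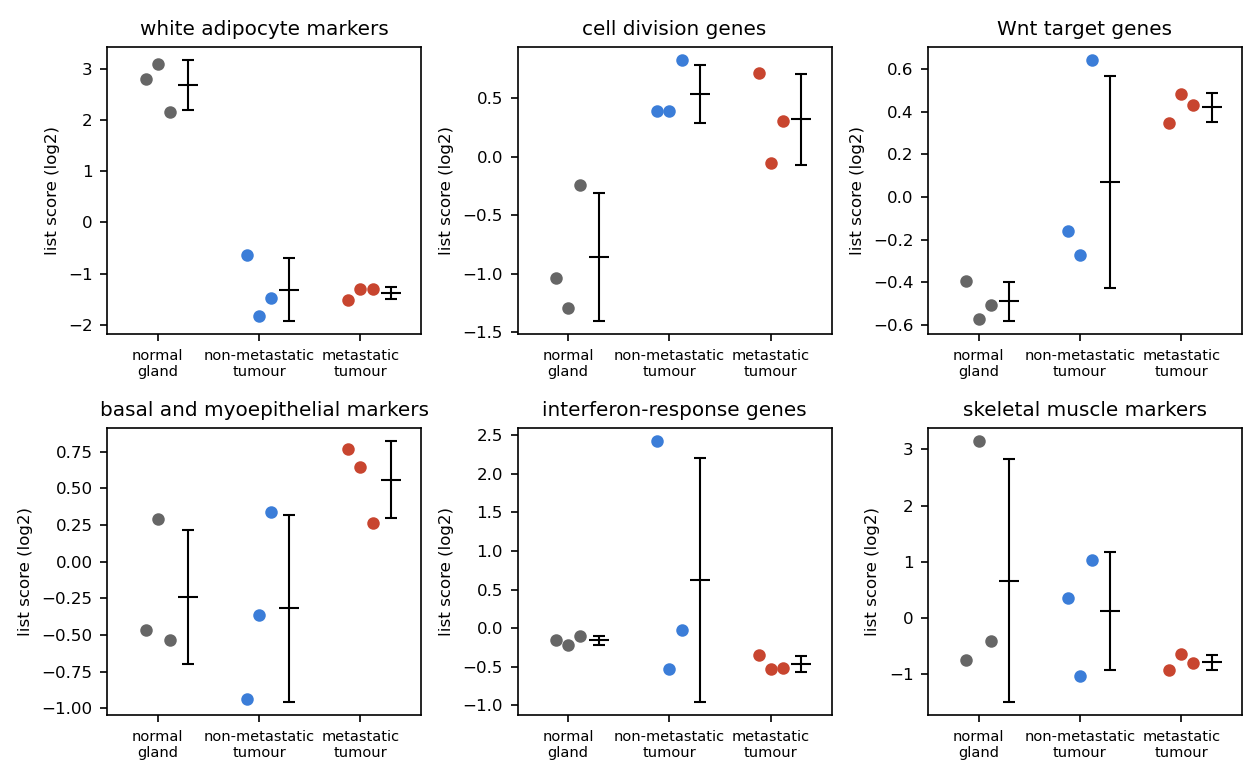
List scores (log2) of 6 gene lists on the 9 arrays, each the mean over the list's genes of the value minus the gene's mean over all arrays. Points are arrays, and the bar beside each group is its mean with the SD (n = 3). White adipocyte scores lie between 2.16 and 3.11 in normal glands and are negative in all 6 tumours, the interferon-response score of non-metastatic tumour 1 is 2.43, and the skeletal muscle score of normal gland 2 is 3.15.

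Against normal gland, several of the lowest values in non-metastatic tumours were those of fat-related genes. Ucp1, the uncoupling protein of brown fat, fell by 6.59 on the log2 scale (SE 0.18, adjusted p = 5.0e-06), and Lep, which encodes the adipocyte hormone leptin, fell by 5.95 (SE 0.52). All 18 measured white adipocyte markers fell, over all genes and when adjusted over the list alone, with a median of -4.11. Camera gave adjusted p = 6.9e-19, and adjusted p = 0.26 with an estimated correlation. Of 12 fatty acid synthesis enzymes, 9 fell and 3 did not pass, and 10 fell when adjusted over the list alone (camera adjusted p = 9.2e-10, and adjusted p = 0.26 with an estimated correlation). Upward, Stk26, a protein kinase, rose by 3.10 (SE 0.30), and Nkd2, a feedback inhibitor of Wnt signalling, rose by 2.98 (SE 0.41). Of 29 cell division genes, 24 rose and 5 did not pass, and 28 rose when adjusted over the list alone (camera adjusted p = 8.7e-11, and adjusted p = 0.52 with an estimated correlation), with Kif11, a mitotic spindle motor, at 1.92 (SE 0.33). Of 26 Wnt target genes, with a median of 0.66, 5 rose, 2 fell and 19 did not pass, and 8 rose and 3 fell when adjusted over the list alone, and camera did not call the list (adjusted p = 0.15, and adjusted p = 0.83 with an estimated correlation). Of 28 cell adhesion molecules, with a median of 0.49, 6 rose and 22 did not pass, and 10 rose and 1 fell when adjusted over the list alone, again without a camera call (adjusted p = 0.071, and adjusted p = 0.49 with an estimated correlation). Without non-metastatic tumour 3 the medians of these 2 lists were 0.31 and 0.32, and without non-metastatic tumour 1 that of cell adhesion was 0.76.

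With limma, 3288 genes passed the threshold in this comparison, 1959 higher and 1329 lower in non-metastatic tumours, and 203 of them had predicted or uninformative symbols. A minimum change of 1 on the log2 scale left 1215 genes and turned the balance, with 460 higher and 755 lower. The balance also moved with the scaling, to 2900 higher and 1078 lower with median centring and 1570 higher and 1249 lower with quantile normalisation. The count was 1345 without normal gland 1, 1517 without normal gland 2 and 1524 without non-metastatic tumour 2. It was 1533 with only the groups compared in the fit and 5360 with array weights.

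Fat-related genes were also lower in metastatic tumours than in normal gland. Ucp1 fell by 6.94 (SE 0.18, adjusted p = 3.2e-06) and Adipoq, the adipocyte hormone adiponectin, by 5.31 (SE 0.55, adjusted p = 0.0024). All 18 white adipocyte markers fell, over all genes and when adjusted over the list alone (median -4.38, camera adjusted p = 1.1e-20, and adjusted p = 0.18 with an estimated correlation). Coch rose by 4.39 (SE 0.31, adjusted p = 3.6e-04), Nkd2 by 4.08 (SE 0.41, adjusted p = 0.0022) and Chad, which encodes the cartilage matrix protein chondroadherin, by 4.08 (SE 0.66, adjusted p = 0.011). Of 29 cell division genes, 16 rose and 13 did not pass, and 27 rose when adjusted over the list alone (camera adjusted p = 1.2e-09, and adjusted p = 0.57 with an estimated correlation). Among Wnt target genes, with a median of 0.76, 8 of 26 rose, 1 fell and 17 did not pass, and 13 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0026, and adjusted p = 0.57 with an estimated correlation). Of 28 cell adhesion molecules, with a median of 0.93, 6 rose and 22 did not pass, and 13 rose when adjusted over the list alone, with Dsc2, a desmosomal cadherin, at 2.92 (SE 0.47). Camera gave adjusted p = 3.5e-04 for cell adhesion, and adjusted p = 0.23 with an estimated correlation.

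With limma, 2332 genes passed the threshold here, 1284 higher and 1048 lower in metastatic tumours, 139 of them with predicted or uninformative symbols. A minimum change of 1 on the log2 scale left 966 genes, 366 higher and 600 lower. Median centring gave 1728 higher and 848 lower, and quantile normalisation 1011 higher and 1013 lower, so the balance depends on the scaling. The count fell to 793 without normal gland 1, to 861 without normal gland 2, and to 627, 1070 and 639 without metastatic tumours 1, 2 and 3. In each of these 5 fits more genes were lower than higher, with 225 higher and 402 lower without metastatic tumour 1. It was 6498 with array weights and 3839 at an adjusted p under 0.1.

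Over both tumour groups together, several immune and vascular markers were lower than in normal gland beside the fat-related genes. Of 7 mast cell markers, 5 fell and 2 did not pass, and 6 fell when adjusted over the list alone, with Mcpt4, a mast cell protease, at -4.72 (SE 0.70) and Tpsb2, a tryptase, at -3.17 (SE 0.41). Camera gave adjusted p = 2.9e-05 for this list, and adjusted p = 0.46 with an estimated correlation. Of 15 blood endothelial markers, 6 fell and 9 did not pass, and 13 fell when adjusted over the list alone (camera adjusted p = 4.4e-07, and adjusted p = 0.49 with an estimated correlation), with Kdr, a receptor for vascular endothelial growth factor, at -1.54 (SE 0.25). Among T and natural killer cell markers, 6 of 16 fell and 10 did not pass, and 6 fell when adjusted over the list alone (camera adjusted p = 8.8e-04, and adjusted p = 0.63 with an estimated correlation). Among Wnt target genes, 11 of 26 rose, 1 fell and 14 did not pass, and 13 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.023, and adjusted p = 0.71 with an estimated correlation). The Wnt target call was lost without normal gland 3 or without non-metastatic tumour 3, where its adjusted p reached at most 0.071. Tnfrsf19, a receptor of the tumour necrosis factor family, rose by 2.33 (SE 0.40), and the member that fell was Twist1, a mesenchymal transcription factor, at -1.31 (SE 0.23).

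Cdh1, which encodes the adherens junction protein E-cadherin, rose by 1.15 (SE 0.17, adjusted p = 0.0043) and Krt7, a keratin of simple epithelia, by 1.90 (SE 0.35, adjusted p = 0.0091), over 6 tumours against 3 normal glands. Of 20 luminal epithelial markers, 7 rose, 1 fell and 12 did not pass, and 8 rose and 3 fell when adjusted over the list alone, while camera did not call the list (adjusted p = 0.12, and adjusted p = 0.81 with an estimated correlation). The list's score was -1.15 in normal gland 2 against 0.014 and 0.129 in normal glands 1 and 3, and between -0.281 and 0.668 in tumours. Without normal gland 2 the list's median difference shrank from 0.99 to 0.29, while Cdh1 (adjusted p = 0.011) and Krt7 (adjusted p = 0.038) still passed. Milk proteins and secretory genes had 0 of 14 members past over all genes and 0 adjusted over the list alone (camera adjusted p = 0.997). Their scores were lowest in normal gland 2, at -2.49, and metastatic tumour 2, at -2.81. The list's median difference of 0.46 became -0.89 without normal gland 2 and 1.08 without metastatic tumour 2. Limma gave 3980 genes past the threshold over all tumours, 2385 higher and 1595 lower, 255 of them with predicted or uninformative symbols, and 26.0% of all genes had no overlap between groups where chance gives 2.38%. A minimum change of 1 on the log2 scale left 455 higher and 747 lower, and median centring gave 3283 higher and 1303 lower. The total was 1991 without normal gland 1, 1898 without normal gland 2 and 7603 with array weights.

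Set side by side, the changes of the 2 tumour groups against normal gland had r = 0.875 and rho = 0.826 across 17478 genes, which are not independent replicates, and 82.8% of genes had the same sign. In both comparisons 1019 genes rose and 890 fell, and 0 genes were called in opposite directions. Both comparisons use the same 3 normal glands, which raises such values. Simulated groups without change set against the same controls gave the same sign in a mean of 66.0% of genes, a mean r of 0.446, ranging from -0.91 to 0.98, and a mean covariance of 0.045 (SD 0.047) against the 0.414 observed. Coch and Scgb1b27 lay apart from the diagonal, at 4.39 and 5.24 in metastatic tumours, while the Coch difference between the tumour groups, and not that of Scgb1b27, passed its own test. The change of Scgb1b27 against normal gland (adjusted p = 0.029) was lost without normal gland 1, normal gland 2 or metastatic tumour 1, with adjusted p of at most 0.089 over its alternatives.

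**Figure D3:**
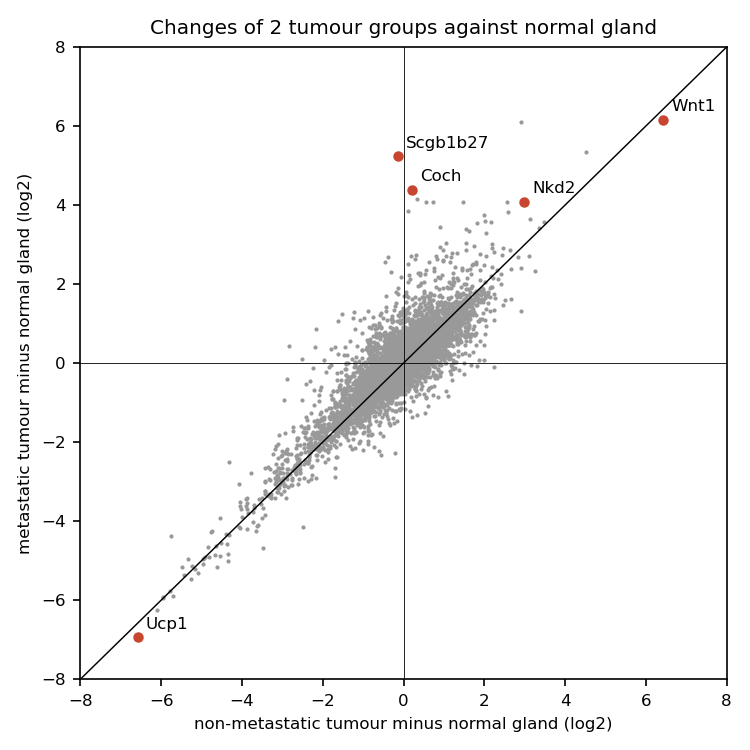
Log2 change of each of 17478 genes in non-metastatic tumours (horizontal axis) and metastatic tumours (vertical axis) against normal gland, with the line of equal change. Grey dots are genes, and the named ones are drawn in red. Wnt1 (6.43 and 6.16) and Ucp1 (-6.59 and -6.94) lie near the line, while Coch and Scgb1b27 lie far above it, at 4.39 and 5.24 on the vertical axis.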

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

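The counts over other splits of the arrays were chosen before their results were seen, and the other tests below only after. For the test against vascular smooth muscle the contractile genes' values had been seen, and those of the pericyte and vascular genes as a list had not. Of these 14 genes, 1 was also in a list fixed earlier.

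Coch differed between the tumour groups by 4.18 on the log2 scale (SE 0.31), which also measures how far its changes from normal gland, 0.21 in non-metastatic and 4.39 in metastatic tumours, lay apart. Probe sets without a single gene symbol, which the comparisons above do not use, held 760 that were higher and 579 that were lower in all tumours against normal gland, of 11579 past the filter, and 0 that differed between the tumour groups.

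For metastatic against non-metastatic tumours, 3 arrays against 3 give only 10 splits, too few for a share under 0.05. The real split gave 1 gene, 3 splits gave as many or more, and the highest other gave 3 genes. For gene lists 4 splits gave as many as the real 15, and the highest other gave 18. Non-metastatic tumours against normal gland gave 3288 genes in the real split, 1 of the 10, and the highest other gave 0. Their 10 lists were reached in all 10 splits, and the highest other gave 18. Metastatic tumours against normal gland gave 2332 genes in the real split, 1 of the 10, and the highest other gave 0. Their 14 lists were reached in 4 splits, with 17 as the highest other. These sets of 10 splits too are too few for a share under 0.05.

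All tumours against normal gland have 84 splits. In a fit of these groups alone the real split gave 4161 genes and the highest other gave 1, so a random split of the arrays is excluded as the source of that count. For lists 45 of the 84 splits gave as many as the real 12, with 22 as the highest other, so a random split is not excluded.

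The 5 contractile genes of the basal list were higher in metastatic than in non-metastatic tumours by 1.93 on the log2 scale (SE 0.62, 6 tumours), mostly from non-metastatic tumours 1 and 2, at 7.94 and 7.54, below normal glands at 8.98 to 10.04, while metastatic tumours lay at 10.11 to 10.49. The contractile difference exceeded that of 14 pericyte and vascular genes, 0.23 (SE 0.44), by 1.70 (SE 0.51), but the 5 genes were picked after their values were seen, from the higher end of the list, and are themselves smooth muscle markers, so the bound of 2 SE set for excluding vascular smooth muscle and pericytes was wrong, and more of these cells cannot be told apart from a change in basal cells. Blood endothelial markers had a median difference of 0.34, with 14 of 15 positive (camera adjusted p = 0.0011, and adjusted p = 0.71 with an estimated correlation), which settles nothing, since the median was 0.12 without metastatic tumour 2 and 0.18 without non-metastatic tumour 2, with the call lost in both. Basal keratin and adhesion genes (8 genes, all in lists fixed earlier) differed by 0.38 (SE 0.63), and the contractile difference exceeded theirs by 1.55 (SE 0.92), so a different share of basal epithelial cells cannot be told apart from a change within them. The metastatic status that the labels record stays among the open explanations, untested.

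Normal gland 2 stood apart in muscle, skin and milk genes. A list of 16 other skeletal muscle genes was higher there than in the mean of the other normal glands by a median of 2.37, with 15 of 16 higher, so skeletal muscle in the tissue piece is a candidate source. A list of 12 other skin and hair genes had a median of 0.83, with 8 higher and the highest at 6.92, which leaves skin in the piece open. Its Wnt1 value of 5.45 lay far below the lowest tumour, at 11.20, which argues against a tumour under a normal label. No biological explanation was tested.

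Interferon-response genes were high in non-metastatic tumour 1, with a list score of 2.43 against at most -0.02 in the other tumours. The highest normal gland scored -0.105 (SD of normal glands 0.057), so tissue like these glands would not give such a score. They came from other, wild-type mice, so gland of the same mouse in the tumour piece cannot be excluded. A higher number of T and natural killer cells stays open. Non-metastatic tumour 1 scored 0.356 for them, above the other tumours (at most -0.114). Although normal glands reached 0.479 with low interferon scores, they are another tissue and exclude nothing. Infection and other differences between the mice stay untested.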

How the results depend on the processing

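The ages without each tumour were added after the data were seen, and all other alternatives were planned. None of the named genes, and none of the lists called with all arrays, changed direction while past the threshold. Lists not called with all arrays were not followed in this way. Fibroblast and matrix genes, not called between the tumour groups, had a median of -0.49 without non-metastatic tumour 2 and 0.77 without non-metastatic tumour 3. The age differences changed sign, and the balance of genes higher and lower turned under the settings named with each count. A count was taken as the same within 1.5 times of its value with all arrays, a tested value on the same side of the threshold, and an untested one, such as an age difference, within 1 SD even where its sign turned. By these limits, among counts and other results 152 values stayed the same, 7 became stronger and 26 weaker. Among values of the lists called with all arrays 644 stayed and 121 weakened. Among gene values 8141 stayed, 90 strengthened and 379 weakened.

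Between the tumour groups 0 genes passed with only the groups compared in the fit (857 at an unadjusted p under 0.05). Age at collection as a covariate, added to that fit without the normal glands, also gave 0 (927 at an unadjusted p under 0.05). With each array left out, between 0 and 40 genes passed. Against normal gland, array weights gave 5360 genes in non-metastatic tumours, 6498 in metastatic tumours and 7603 over all tumours. Only the groups compared gave 1533 for non-metastatic tumours. An adjusted p under 0.1 gave 3839 for metastatic tumours, where more genes qualify by construction. A minimum log2 change of 1 gave 1215, 966 and 1202, where fewer genes qualify by construction. With each array left out the counts ran from 1345 to 3714, from 627 to 2832 and from 1898 to 4117, and the highest, above those with all arrays, came without normal gland 3. For all changes but those from that minimum and from the adjusted p under 0.1, the cause was not tested.

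With the replicate number as a block, metastatic tumours against normal gland gave 1299 genes, 632 higher and 667 lower. Deviations of arrays with the same number correlated between -0.28 and 0.17. No values for arrays with different numbers were set beside these, so a tie between arrays of the same number cannot be excluded.

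With an estimated correlation 0 lists passed in each of the 4 contrasts, and fry, which tests each list on its own, passed 0 between the tumour groups, 10 for non-metastatic and 5 for metastatic tumours against normal gland, and 11 for all tumours. With each array left out, lists past numbered 10 to 19, 9 to 13, 12 to 17 and 12 to 15, and the side-by-side r was 0.796 to 0.901. The age differences ran from -37.7 to 28.3 days at collection, from -47.5 to 9.5 at onset and from 2.5 to 25 between them. With signals near background, the filter removed 4702 genes.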

Other observations

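FGF pathway genes moved in both directions in tumours. Of 18 measured members, 4 rose, 2 fell and 12 did not pass over all tumours against normal gland, and 5 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.76, and adjusted p = 1.00 with an estimated correlation). Etv5, a transcription factor induced by FGF signalling, rose by 2.37 (SE 0.34, 6 tumours against 3 glands) and Dusp6, a phosphatase that restrains ERK, by 1.52 (SE 0.24), while Fgf10, a growth factor made by mesenchymal cells, fell by 1.57 (SE 0.14).

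Of 17 mesenchymal transition genes, 5 fell in tumours and 12 did not pass, and 7 fell when adjusted over the list alone (camera adjusted p = 0.0061, and adjusted p = 0.63 with an estimated correlation). Zeb1, a repressor of epithelial genes, fell by 1.60 (SE 0.30) and Twist1, a mesenchymal transcription factor, by 1.31 (SE 0.23). Without normal gland 2 the list's median shrank from -0.65 to -0.40. Its score in metastatic tumour 2, at 0.23, lay above that of normal gland 3, at 0.17. Fat-related, fibroblast and blood endothelial genes were mostly lower too, so fewer such cells cannot be told apart from lower expression within cells. The fibroblast and matrix score was not lower in every tumour. It was 0.68 in non-metastatic tumour 3, within the 0.62 to 0.77 of normal glands, and between -1.73 and 0.26 in the other tumours. Of 21 fibroblast and matrix genes 4 fell and 17 did not pass, and 4 fell when adjusted over the list alone (median -1.20, camera adjusted p = 9.4e-04, and adjusted p = 0.75 with an estimated correlation), and 2 genes, Fn1 and Sparc, are in both lists. Of 8 brown adipocyte markers 6 fell and 2 did not pass, and 6 fell when adjusted over the list alone (camera adjusted p = 2.1e-07, and adjusted p = 0.21 with an estimated correlation), with Elovl3, a fatty acid elongase, at -6.17 (SE 0.24). Of 12 B cell and plasma cell markers 4 fell and 8 did not pass, and 4 fell when adjusted over the list alone, with Cd37, a tetraspanin of B cells, at -1.14 (SE 0.22). Camera gave adjusted p = 0.0095 for this list, and adjusted p = 0.49 with an estimated correlation.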
